A study of Caenorhabditis elegans with 3 samples.

How the data were processed

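Expression was measured in whole worms with 1 Affymetrix array per condition (control, GO and rGO), so no test across replicates was possible. Per the labels' protocols, the worms came from synchronised cultures on bacterial plates, and RNA was purified with a silica column kit. Per the labels, 300 ng of total RNA per sample was amplified and biotin-labelled with a whole-transcript kit. The control title, unlike those of the exposed samples, does not state 24 h; the shared treatment protocol does. The array's name is not given in the sources used here; the control probe sets read the 3′, middle and 5′ parts of control transcripts.

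The deposited values are log2 expression values per probe set, and per the submitters' processing notes GCOS, Affymetrix Expression Console and RMA were used, with no version given. RMA corrects the background, quantile-normalises the probes and summarises each probe set by median polish over the arrays. Such processing makes array-wide distributions equal, so a general rise or fall of RNA per worm cannot be seen. With 3 arrays, median polish also gives exact ties: 20.9% of the probe sets had identical GO and control values, 19.8% identical rGO and control values and 25.1% identical GO and rGO values, and 2200 genes were equal on all 3 arrays. A difference of 0.00 therefore often means that the summary did not resolve the arrays. Scanner files were not used here, and the precision is limited by the number of arrays. No signal detection call was used.

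Of 22625 probe sets, 77 are the maker's controls, 20766 carry 1 gene, 887 several and 895 none in the platform annotation of 2016. For 20701 single-gene probe sets the gene identifier was found in a RefSeq table of assembly WBcel235, which gave current symbols; no coordinates were used, as the annotation names no assembly. Probe sets with several genes or none entered no comparison. The values of probe sets of 1 gene were averaged, which gave 17118 genes, 2981 of them with more than 1 probe set. The median SD between probe sets of a gene was 0.21 for GO minus control, 0.38 for rGO minus control and 0.30 for GO minus rGO, which describes probe sets and not worms. By the maker's naming, 5803 single-gene probe sets share probes between transcripts, and values of near-identical families such as the major sperm proteins are therefore not separate.

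For each comparison, genes entered when the brighter of its 2 arrays was at or above 6.79, the median of all gene values. A gene was counted at a log2 difference of at least 1, a rule of size and not a test. Folds are given as "at least" where the dimmer array was below 6.24, the highest of 8 probe sets with no expected target (range 3.80 to 6.24); the fold is then taken against 6.24. Named genes are the 10 with the largest difference per direction and comparison, and up to 4 genes per list with the largest absolute difference. Other named genes, such as col-19 against control, were taken after their values were seen. Disagreement of over 1 unit between probe sets is stated.

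The 43 lists cover signalling, reproduction, stress, detoxification, immunity, metabolism and tissues. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with replacement, and lists outside percentiles 2.5 to 97.5 are described as outside the middle 95%. This describes these arrays and is no test of an exposure. The lists, the size rule, the floor and the alternatives were set before the data were examined. That list medians also use the floor was settled after list medians without a floor had been seen; values with no floor stand among the alternatives. Overlap of the GO and rGO differences was set beside 100 simulations of unchanged arrays that share 1 control array. All 3 simulated arrays had noise taken from the GO minus rGO differences, which does not bound the control array's own noise.

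The gap between 3′ and 5′ probe sets of control transcripts was taken per pair of probe sets, with 4 poly-A transcripts read by 2 versions each, where both ends were above 6.24 on at least 1 array, a limit set after the values were seen. How the labelled product of a whole-transcript kit bears on these gaps is not given in the sources used here, so they compare the arrays and do not measure RNA integrity. The counting and list steps were tested on simulated data for GO against control over 17118 genes. All of 200 genes changed by 2 log2 units (100%) were counted in the right direction, 3 of 8652 unchanged genes above the floor were counted at a simulated SD of 0.21 per array, and 5.17% of 20000 null lists of 30 genes fell outside the middle 95%. That SD was taken over genes from the median absolute difference between the GO and rGO arrays. The low count of 3 follows from it and does not measure chance differences between cultures. The 200 changed genes were drawn from those with mean expression over 1 unit above the floor, so dim genes were not tried. The null lists held random genes, so lists of related genes were not tried either. Alternatives were a further quantile normalisation, centring on the median, removal of a loess trend (span 0.3), no floor, a floor at the 75th percentile (8.92), the brightest probe set per gene, thresholds of 1.5-fold and 3-fold, and random lists unmatched or matched in 10 bins. Leaving out probe sets that share probes was added after seeing the data, as were a list of late embryonic epidermis genes and one of fasting-induced genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.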

Results

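Whole young adult hermaphrodites of the wild-type nematode Caenorhabditis elegans, 3 days old, were incubated for 24 h at 20 °C without food in a salt medium. One set of worms was the control, one was exposed to GO and one to rGO. The labels give these abbreviations only. The published study behind the series concerned graphene oxide and reduced graphene oxide, a form of GO with part of its oxygen groups removed. The exposure concentration is not given in the sources used here. Total RNA of each set was labelled with biotin and hybridised to 1 Affymetrix expression array, so each of the 3 conditions has 1 array. No spread between replicates exists, no p-value or standard error is given, and every difference below compares single arrays. Differences are in log2 units of the deposited values, with 1 unit being 2-fold, and "higher" or "lower" describes the arrays alone.

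The 3 arrays had nearly equal distributions, with medians of 6.87 (control), 6.92 (GO) and 6.86 (rGO) over 22548 probe sets. Across genes, the GO and rGO arrays were closer to each other (Pearson r = 0.978) than either was to the control array (r = 0.943 for GO and 0.956 for rGO). Genes are not independent replicates. The control probe sets were not equal between arrays. All 24 probe sets for bacterial poly-A transcripts, which are added to the RNA before labelling, were lower on the GO array than on the control array (median -1.55) and all were lower on the rGO array (median -0.98). All 18 hybridisation control probe sets were lower as well, with medians of -0.62 on the GO array and -0.93 on the rGO array. The gap between the 3′ and 5′ ends, over 8 pairs of probe sets that read 4 poly-A transcripts in 2 versions each, had a median of 1.36 on the control array, 2.14 on the GO array and 1.56 on the rGO array. For 8 pairs of probe sets at both ends of worm transcripts, the median gap was 1.88, 2.57 and 1.16, respectively. The GO gap exceeded the control gap in both versions of 4 of 4 poly-A transcripts and in 6 of 8 worm pairs, whereas the rGO gap was below the control gap in 8 of 8 worm pairs. On the GO array most 5′ probe sets of the poly-A pairs were below 6.24, for example LysX at 5.36. The poly-A gaps and the count of 4 are therefore not exact. For 1 lys version both ends were below it (6.15 and 4.88), so a wider gap was not established there. The 5′ end of the worm catalase pair was below it on the control and GO arrays (5.52 and 5.23). Values below 6.24 were not above background, so a gene given as "at least" has no exact fold and its place in an order of differences is not exact.

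**Figure D1:**
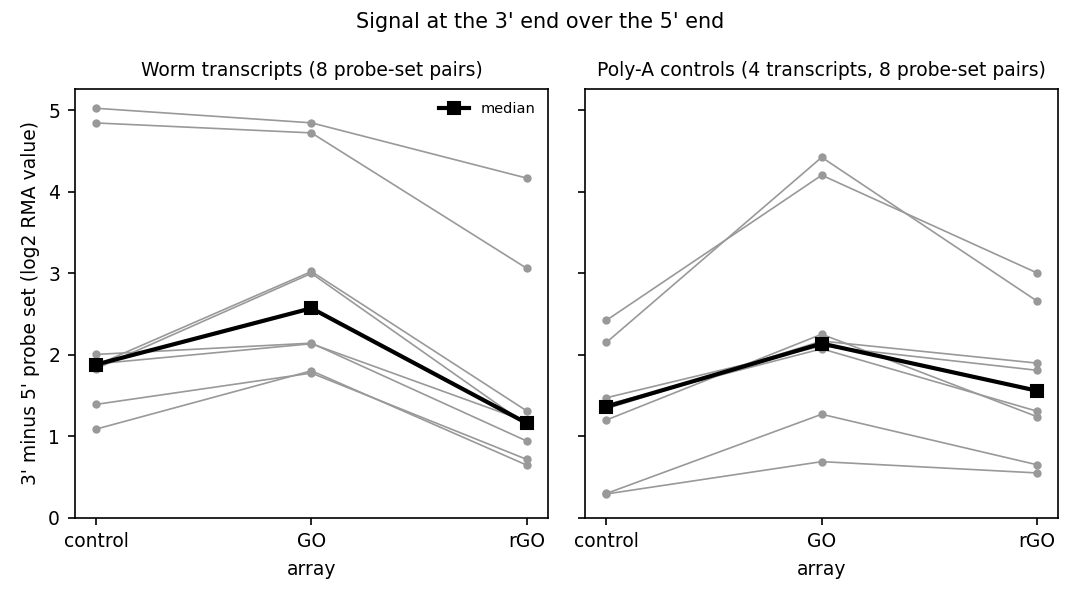
Signal at the 3′ end minus signal at the 5′ end (vertical axis, log2 units) on the control, GO and rGO arrays, for 8 pairs of worm probe sets (left) and 8 pairs that read 4 bacterial poly-A control transcripts (right). Grey lines are pairs and black squares their medians, which for the poly-A pairs are 1.36, 2.14 and 1.56. Most poly-A 5′ probe sets were below 6.24 on the GO array, so those gaps are not exact.

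The first comparison asked which transcripts differed in worms exposed to GO; the study's interest is known to lie in reproduction and in Wnt and MAP kinase signalling. Most sperm transcripts, 58 of 124 cuticle collagens and 25 of 43 UDP-glucuronosyltransferases were at least 2-fold lower on the GO array than on the control array. Of 27 epidermal markers, 14 were at least 2-fold higher. Of 9303 genes above the floor on dim genes, 784 were at least 2-fold higher and 908 at least 2-fold lower, and 165 and 381 of these differed at least 4-fold. The 10 genes with the largest positive differences of the deposited values included mtre-1 (+6.95, at least 58.0-fold), cut-3, a cuticlin of the cuticle (+6.15, at least 42.6-fold), nlp-39, a neuropeptide-like gene (+5.89, at least 22.6-fold), and the collagen gene dpy-14 (+5.18, 36.3-fold). The collagens col-165 and col-74 were higher by 4.90 and 4.60, phat-5, a gene of the pharyngeal glands, by 4.95, and Y110A2AL.4 and C46A5.4 by 4.46 and 4.40 (at least 17.4-fold and 8.21-fold). The chitinase-family gene cht-5 was higher by 4.83 (at least 23.2-fold), although its 2 probe sets differed by 1.81. The largest negative differences belonged to the collagens col-129 (-6.34, 81.1-fold), col-139 (-5.99) and col-81 (-5.34), to spig-20 (-5.65), ZK1248.4 (-5.45, at least 41.5-fold) and F58A6.9 (-5.35), to the sperm genes msp-50 and msp-152 (both -5.22), to the cytochrome P450 gene cyp-35A4 (-5.15, at least 16.8-fold) and to the transthyretin-related ttr-14 (-5.06, at least 20.8-fold).

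Sperm genes stood apart from the other genes of reproduction. All 23 measured major sperm protein genes, which encode the motility protein of nematode sperm, were at least 2-fold lower on the GO array, with a median of -4.57. Examples were msp-50, msp-152 and msp-38 (-5.01, 32.2-fold). Their probe sets share probes within this nearly identical family, so the 23 values are not separate measurements. Among 18 sperm genes outside this family, 13 were at least 2-fold lower, 5 were under 2-fold and none was higher, with a median of -1.78. The MSP-domain genes msd-4 (-4.78, 27.5-fold) and msd-2 (-4.58, 23.9-fold) and the sperm phosphatase gene gsp-3 (-3.89, at least 10.3-fold) were among the lowest. Both medians lay below the middle 95% of expression-matched random lists. The 34 oocyte and eggshell genes had a median of 0.13, with 2 at least 2-fold higher (cav-1, a caveolin, +2.15, and the germline Notch receptor glp-1, +1.10) and none lower. The 36 genes of meiosis and P granules had a median of 0.00 and all were under 2-fold. Among 5 vitellogenins, the yolk proteins, vit-1 was lower by 8.36-fold (-3.06) and the other 4 were under 2-fold, for example vit-2 at 0.30 and vit-6 at 0.35. Of 32 cell cycle genes, 2 were higher, the kinase inhibitor cki-1 (+1.80) and the Aurora kinase air-1 (+1.02), and the median of 0.31 lay above the middle 95% of random lists. With the brightest probe set per gene this median was 0.15, inside the middle 95%. Of 11 early embryonic genes, nhr-25, a nuclear receptor of the epidermis, was higher (+1.58, with probe sets 1.97 apart) and 10 were under 2-fold.

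For the signalling pathways, Wnt genes had a median of 0.27 over 27 genes, inside the middle 95% of random lists. The Frizzled receptor cfz-2 (+1.92) and the Wnt ligands cwn-2 (+1.89) and cwn-1 (+1.80) were at least 2-fold higher and none was lower. After a further quantile normalisation the Wnt median was 0.40, above the middle 95%. Of 25 genes of the MAP kinase cascades, jnk-1, a c-Jun N-terminal kinase (+1.86), and the ubiquitin ligase gene rpm-1 (+1.19) were higher, 23 were under 2-fold, and the median was 0.12. The 15 TGF-beta genes had a median of 0.23, with the ligand gene unc-129 higher (+2.43). The 16 insulin/FOXO genes had a median of 0.32, with ist-1, the insulin receptor substrate gene, higher (+1.07). None of these 3 medians left the middle 95%.

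Collagens were lower more often than higher. Of 124 collagens above the floor, 58 were at least 2-fold lower and 9 at least 2-fold higher, with a median of -0.96. Against col-129 and col-139 stood dpy-14 and col-165 on the higher side. The adult collagen col-19 had a log2 level of 12.17 on the control array and 7.97 on the GO array. The median 3′ to 5′ gap of the worm control pairs was wider on the GO array, at 2.57 against 1.88. On the rGO array that gap was narrower, at 1.16, yet collagens were also lower there, with a median of -1.05 (66 lower and 5 higher of 123). Of 27 hypodermis and seam markers, 14 were at least 2-fold higher and 3 lower, with a median of 1.12, above the middle 95% of random lists. The matrix proteins noah-1 (+3.37, 10.3-fold) and noah-2 (+2.59), the hedgehog-related wrt-1 (+3.04) and the patched-related ptr-4 (+2.75, at least 3.08-fold) were higher, whereas the hedgehog-related grd-3 was lower (-2.99). Without probe sets that share probes the median of this list was 0.33, inside the middle 95%.

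Enzymes of xenobiotic metabolism were lower on the GO array more often than higher. Of 43 UDP-glucuronosyltransferases, which attach sugars to foreign compounds, 25 were at least 2-fold lower and 3 higher, with a median of -1.23; ugt-8 (-4.26, 19.2-fold), ugt-63 (-4.19, at least 7.26-fold) and ugt-13 (-3.97) were among the lowest. Of 25 glutathione S-transferases, 12 were lower and 1 higher (median -0.97), among them gst-26 (-3.01) and gst-4 (-2.68). Of 32 cytochrome P450s, 11 were lower and 3 higher (median -0.33), and cyp-35A4, cyp-35A3 (-4.44) and cyp-35C1 (-4.38) were the lowest. All 3 medians lay below the middle 95% of random lists, and the poly-A control probe sets were also lower on this array, by a median of 1.55. The P450 median was 0 with no floor on dim genes. Of 27 ABC transporters, 4 were lower, with pgp-1, a P-glycoprotein, at -3.04 (at least 6.15-fold), and 1 was higher; their median was -0.01.

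Stress genes showed single large differences, and 3 immune lists lay below the middle 95%. The metallothionein mtl-1 was higher by 8.58-fold and the cadmium-responsive cdr-4 lower by 5.78-fold (-2.53), with a median of -0.04 over 12 metal response genes. Of 22 cytosolic heat shock genes, hsp-12.6 (+3.63) and hsp-12.1 (+1.83) were higher and hsp-70 was lower (-3.04, at least 7.70-fold), with a median of -0.08. In the antioxidant list gcs-1, the rate-limiting enzyme of glutathione synthesis (+1.88, with probe sets 1.12 apart), and the ferritin ftn-1 (+1.61) were higher, the methionine sulfoxide reductase msra-1 was lower (-1.59), and 20 of 23 genes were under 2-fold. The medians of the lists for endoplasmic reticulum stress (0.11), mitochondrial stress (0.01), proteasome (0.08), DAF-16 targets (0.11) and germline apoptosis with DNA damage (0.10) were inside the middle 95%. Autophagy genes had a median of 0.29, above it, with atg-16.2 (+1.71) and sqst-1 (2.29-fold) higher; without probe sets that share probes the median was 0.002. Epidermal antimicrobial peptides had a median of -0.83, with 6 of 14 lower, including nlp-26 (-2.51) and nlp-27 (-1.53). PMK-1 pathway targets had a median of -0.36, with the infection response genes irg-4 (-2.85) and irg-5 (-1.83) among 5 lower genes of 16. Of 56 C-type lectins, 13 were lower and 10 higher, with a median of -0.08; this median and the 2 before it lay below the middle 95%, but the lectin median was 0 with no floor on dim genes. Of 22 lysozymes and saposins 9 were lower, including spp-4 (-3.25), and 5 higher, including spp-31 (+3.00), with a median of 0.16 inside the middle 95%. With the floor at the 75th percentile that median was -0.44, below it.

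In lipid metabolism, the stearoyl-CoA desaturase fat-7 (-2.86, 7.28-fold) and the elongases elo-6 (-2.31) and elo-5 (-2.22) were lower. The fatty acid list had 7 lower and 3 higher genes of 25 and a median of -0.24, which became 0.01 without probe sets that share probes. In the fasting response list 8 of 22 genes were lower and 2 higher (median -0.61), with acdh-2, an acyl-CoA dehydrogenase, at -2.52 and the lipase lipl-2 at +1.33. This list is not limited to fasting-induced genes, so its median gives no direction of a fasting response. Its 8 fasting-induced members above the floor had a median of 0.044. All 74 ribosomal protein genes (median 0.17) and all 40 respiratory chain genes were under 2-fold. The respiratory chain median of -0.04 lay below the middle 95% of random lists. After a further quantile normalisation it was 0.002 and still below. It lay inside with unmatched random lists and, at -0.07, without probe sets that share probes. Among tissue markers, neuron markers had a median of 0.69, above the middle 95%, with 6 of 24 higher, including ric-4, a SNAP-25 homologue (+1.94). Pharynx markers had a median of 0.51, with 5 of 16 higher, and 0.35, inside the middle 95%, without probe sets that share probes. Neuropeptides had a median of 0.37, also above it, with 5 higher and 6 lower of 67. The lower ones included nlp-26 (-2.51), nlp-27 (-1.53) and nlp-33 (-1.06), which are counted also among the antimicrobial peptides. Histones had a median of 0.36, with the linker histone hil-7 higher by 3.78, and 0.19, inside, without probe sets that share probes. Intestine markers had a median of -0.40, with 9 of 29 lower, including far-3 (-2.87) and lbp-6 (-1.98), but the median was -0.06 without probe sets that share probes. Body wall muscle markers (-0.02), somatic gonad and vulva markers (0.22) and coelomocyte and excretory markers (0.35) were inside the middle 95%, although the myosin gene unc-54 was lower (-1.32). Without probe sets that share probes, ribosomal proteins (0.28) lay above and antioxidant enzymes (-0.27) and ABC transporters (-0.29) below the middle 95%, and heat shock genes (-0.15) lay below with the brightest probe set per gene. Body wall muscle markers (-0.07) lay below after a further quantile normalisation. Of the 42 lists with at least 5 genes above the floor, 7 lay above and 13 below the middle 95%. Lists of unrelated genes would put 2.1 outside. These lists hold related genes, some read by shared probes, so 2.1 does not bound what 2 unexposed cultures would give.

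The second comparison asked the same of rGO. At least 2-fold lower than on the control array were 22 of 42 UDP-glucuronosyltransferases, 66 of 123 collagens and, by less than with GO, all 23 major sperm protein genes. At least 2-fold higher were 31 of 69 neuropeptide genes. Of 9097 genes above the floor, 727 were at least 2-fold higher and 899 lower, and 299 of the lower genes differed at least 4-fold. The largest positive differences of the deposited values belonged to nlp-39 (+6.06, at least 25.4-fold), the C-type lectin clec-61 (+4.68, at least 10.9-fold), mtre-1 (+4.52, at least 10.7-fold), the ribosomal RNA gene rrn-3.1 (+4.47) and phat-5 (+4.39). The next were C54C8.12 (+4.36, at least 12.7-fold), C32F10.4 (+4.05), the ubiquitin ligase component skr-5 (+3.98, at least 6.21-fold), cup-16 (+3.90) and T05E12.3 (+3.90). The largest negative differences were those of cyp-35A3 (-5.35, 40.9-fold), cyp-35C1 (-5.28, 38.8-fold), cyp-35A4 (-5.18, at least 16.8-fold), ugt-13 (-4.88, at least 27.7-fold), T13F3.6 (-4.66), F18E3.11 (-4.57, at least 8.82-fold), the collagen col-49 (-4.49, at least 13.6-fold), ugt-63 (-4.48, at least 7.26-fold), spig-20 (-4.47) and the proteoglycan gene cpg-9 (-4.45).

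All 23 major sperm protein genes were at least 2-fold lower on the rGO array, with a median of -1.52, and msp-64 was the lowest (-2.32, 4.98-fold). Of the 18 other sperm genes 11 were lower (median -1.36), including ssp-16 (-2.60) and msd-4 (-2.53). Oocyte and eggshell genes had a median of 0.23 over 34, with glp-1 (+1.21) and the eggshell proteoglycan cpg-3 (+1.11) higher and the zinc finger gene mex-1 lower (-1.29). Meiosis and P granule genes had a median of 0.19, with the Argonaute csr-1 (+1.65), the RNA-binding fbf-1 (+1.57) and pch-2 (+1.21) higher and 33 of 36 under 2-fold. Among vitellogenins vit-1 was lower by 10.5-fold (-3.40) and 4 of 5 were under 2-fold. Cell cycle genes (0.20) and early embryonic genes (0.00) were inside the middle 95%.

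Of 25 Wnt genes, apr-1, the APC-related gene, was higher (+1.03), 24 were under 2-fold and the median was 0.11. MAP kinase genes had a median of 0.19, with the JNK-family kinase kgb-2 higher (+1.57, at least 2.88-fold) and jnk-1 at +0.89. TGF-beta genes had a median of 0.24, with sma-10 (+1.25, at least 2.36-fold) and the SMAD gene sma-2 (+1.24, at least 2.29-fold) higher and lon-1 lower (-1.34). The median of the insulin/FOXO list was 0.46, above the middle 95%, with ist-1 (+1.65) and the insulin-like peptide ins-35 (+1.55) higher and 14 of 16 under 2-fold. It was 0.36 and inside the middle 95% without probe sets that share probes.

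UDP-glucuronosyltransferases had a median of -1.07, with 22 lower and 3 higher of 42, and glutathione S-transferases one of -0.78, with 11 lower and 4 higher of 25; gst-26 was at -3.31 and gst-4 at -2.96. For 33 cytochrome P450s the median was -0.22, inside the middle 95% at percentile 2.56, with 10 lower and 5 higher; after a further quantile normalisation it was -0.28 and below. Against the cyp-35 genes stood cyp-37B1 (+3.82, 14.1-fold). The poly-A control probe sets were lower on this array too, by a median of 0.98. ABC transporters had a median of -0.12, with pgp-1 at -3.68 (at least 6.15-fold). Collagens had a median of -1.05, with 66 lower and 5 higher of 123; col-49 and col-38 (-4.29, at least 19.4-fold) were examples. The hypodermis and seam list had a median of 0.00 and 5 of 23 genes lower, including grd-5 (-3.87). Without probe sets that share probes that median was -0.21, and with the floor at the 75th percentile it was -1.50, both below the middle 95%.

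Of 69 neuropeptide genes, 31 were at least 2-fold higher on the rGO array and 4 lower, with a median of 0.98. Examples were nlp-39, flp-10 (+2.52, 5.73-fold) and nlp-2 (+2.33, at least 4.31-fold), while nlp-26 (-2.40), counted also among the antimicrobial peptides, was lower. Neuron markers had a median of 0.67, with egl-21, a carboxypeptidase that processes neuropeptides (+1.75), and ric-4 (+1.27) among 4 higher genes of 22. Both lists lay above the middle 95%, as did pharynx markers (0.50) and lysozymes and saposins (0.38), in which spp-8 was at +3.20 and spp-4 at -3.40. The lysozyme median was 0.23 and inside after removal of a loess trend and 0 with no floor, and that of pharynx markers was 0.35 and inside without probe sets that share probes. PMK-1 pathway targets had a median of -0.97, with 8 of 16 lower and none higher; irg-4 was lower by 21.6-fold (-4.43) and irg-5 by 10.7-fold (-3.42). Antimicrobial peptides had a median of -0.77. C-type lectins had a median of 0.07 over 62, with 16 higher, including clec-61, clec-264 (+3.05) and clec-7 (+2.85), and 13 lower.

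Fasting response genes had a median of -0.42, with acdh-2 at -3.45 (at least 8.94-fold) and the lysosomal lipases lipl-2 (+3.31, 9.89-fold) and lipl-3 (+2.37) higher. Here too the list is not limited to fasting-induced genes, and its 8 fasting-induced members above the floor had a median of -0.11. The fatty acid list had 7 higher and 7 lower genes of 25, with a median of -0.26. In it fat-3 (+2.13) and fat-4 (+2.11), desaturases of polyunsaturated fatty acids, were higher and elo-5 (-2.85) and elo-6 (-2.71) lower. That median lay below the middle 95%, but was 0 and inside with the floor at the 75th percentile. Intestine markers had a median of -0.28, with 8 of 29 lower, including the intestinal actin act-5 (-2.14); the median was 0.10 without probe sets that share probes. The metallothionein mtl-1 (+3.19) and hsp-12.6 (+3.63) were higher, cdr-4 (-3.25) and msra-1 (-2.54) were lower, and gcs-1 was at +2.07. The lists of antioxidant enzymes (0.02), metal response (-0.03), heat shock (-0.05), endoplasmic reticulum stress (0.18), mitochondrial stress (0.16), proteasome (0.28), autophagy (0.23), DAF-16 targets (0.18), apoptosis (0.09), respiratory chain (0.27), ribosomal proteins (0.26), histones (0.23), muscle (0.02), gonad (0.20) and coelomocytes (0.23) had medians inside the middle 95%. With the brightest probe set per gene, the medians of ribosomal proteins (0.16), respiratory chain (0.27), proteasome (0.25), histones (0.24) and autophagy (0.25) lay above it and that of heat shock (-0.28) below. Ribosomal proteins were at 0.44 and above without probe sets that share probes. Metal response genes were at -0.59 and below with the floor at the 75th percentile. In all, 5 lists lay above and 10 below it as reported. Only 3 genes of the intracellular pathogen response were above the floor, and none reached 2-fold in any comparison.

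The third comparison set the related materials GO and rGO against each other at the same 24 h. The control array was not subtracted, but it entered the shared processing of the values. Their concentrations are not given in the sources used here and may differ. Major sperm protein genes were lower with GO than with rGO, and 15 of 27 epidermal markers were higher. Collagens went both ways, with 20 at least 2-fold higher and 16 lower, the latter including col-129 and col-19. Neuropeptide genes had a lower median with GO, with 61 of 67 under 2-fold. Of 8978 genes above the floor, 502 were at least 2-fold higher with GO and 335 lower, with 95 and 51 at 4-fold. The largest positive differences of the deposited values belonged to ZK1025.3 (+3.27, at least 3.19-fold), cht-5 (+3.15, 8.90-fold), Y102A11A.5 (+3.06, at least 3.94-fold), ZK675.4 (+2.98), dbd-2 (+2.93), Y37A1B.7 (+2.92, at least 3.83-fold), cut-3 (+2.86), F07H5.13 (+2.86), bus-24 (+2.83, at least 4.67-fold) and the small heat shock gene hsp-12.1 (+2.82, 7.07-fold). The largest negative ones were clec-61 (-4.36, at least 10.9-fold), col-129 (-3.86, 14.5-fold), msp-152 (-3.63), msp-38 (-3.48), msp-31 (-3.40), msp-76 (-3.33), the adult collagen col-19 (-3.29, 9.77-fold), msp-50 and msp-33 (both -3.22) and msp-36 (-3.21).

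Of the 23 major sperm protein genes, 22 were at least 2-fold lower with GO (median -2.93), as were 6 of the 11 other sperm genes above the floor (median -1.36), among them msd-2 (-2.42) and msd-4 (-2.25). The median 3′ to 5′ gap of the poly-A control pairs was also wider with GO, at 2.14 against 1.56, but is not exact because most 5′ ends were below 6.24 on the GO array. Of 27 hypodermis and seam markers, 15 were higher with GO and none lower (median 1.18), led by wrt-1 (+2.74, 6.67-fold), ptr-4 (+2.29, at least 3.08-fold), noah-1 (+2.28) and noah-2 (+2.15). Among collagens above the floor, 20 were higher, 16 lower and 68 under 2-fold; dpy-14 was at +2.61. Their median of 0.10 lay above the middle 95%, but was -0.06 with the floor at the 75th percentile. Of 67 neuropeptide genes, 6 were lower with GO and none higher (median -0.58), including nlp-2 (-1.44), nlp-1 (-1.27) and flp-9 (-1.08).

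For GO against rGO the Wnt list had a median of 0.29 over 27 genes, above the middle 95% of random lists. The ligands cwn-1 (+1.62) and cwn-2 (2.80-fold) and the receptor cfz-2 (+1.43) were at least 2-fold higher with GO and 24 were under 2-fold. All 25 MAP kinase genes were under 2-fold (median 0.06), with jnk-1 at +0.97 and kgb-2 at -0.86. The TGF-beta median was -0.27, below the middle 95%, with sma-10 at -1.13 and unc-129 at +1.69, but it was 0.13 with the floor at the 75th percentile and 0.04 with the brightest probe set per gene. Meiosis and P granule genes had a median of -0.16, also below, with csr-1 at -1.04; it was -0.14 and inside without probe sets that share probes. PMK-1 pathway targets had a median of 0.67, above, with irg-5 (+1.58), irg-4 (+1.57) and hpo-6 (+1.24) higher. Below the middle 95% lay also UDP-glucuronosyltransferases (-0.37), antioxidant enzymes (-0.29), proteasome (-0.23), C-type lectins (-0.26), fatty acid genes (-0.39) and the respiratory chain (-0.28). The lectin median was 0 with no floor, and the antioxidant median was -0.21 and inside with the floor at the 75th percentile. In these lists single genes mostly differed by under 2-fold, as did 39 of 40 respiratory chain genes, the ATP synthase gene asb-2 being at -1.33.

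The other lists had medians inside the middle 95% for GO against rGO as reported. The 7 cyp-35 genes had median differences from control of -3.78 for GO and -3.75 for rGO, with cyp-35A4 below background on both exposed arrays. None of 22 glutathione S-transferases reached 2-fold between GO and rGO (median -0.17), nor did any of 28 intestine markers (median -0.13), 74 ribosomal proteins (-0.07), 24 ABC transporters (0.00) or 26 autophagy genes (-0.03). Vitellogenins (0.04), oocyte genes (0.00), cell cycle (0.00), early embryo (0.24), apoptosis (0.03), insulin/FOXO (-0.16), cytochrome P450s (-0.01), metal response (0.05), heat shock (-0.03), endoplasmic reticulum stress (0.00), mitochondrial stress (-0.19), lysozymes (-0.06), antimicrobial peptides (-0.01), DAF-16 targets (-0.09), fasting response (0.01), histones (0.00), muscle (-0.01), pharynx (-0.07), neurons (0.12), gonad (0.06) and coelomocytes (0.03) had medians inside the middle 95%. Members of these lists still differed: of 27 muscle markers 3 were at least 2-fold higher and 5 lower, among them the myosin unc-54 (-1.45), and of 20 fasting response genes 1 was higher and 4 lower, among them lipl-2 (-1.98). Without probe sets that share probes the muscle median was 0.23 and that of neuron markers 0.31, both above the middle 95%. Glutathione S-transferases (-0.20) lay below it after a further quantile normalisation and intestine markers (-0.13) with the brightest probe set per gene. With the floor at the 75th percentile lysozymes (-0.30) lay below it and antimicrobial peptides (0.19) above. With 1 array per material, no interval of the difference can be given, so small differences do not show that the materials act alike.

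The differences of GO and of rGO from control were set against each other over 9454 genes above the floor on any array. They correlated across genes with r = 0.79 (Spearman rho = 0.75) and had the same sign for 83.6% of genes. Both comparisons use the same control array, so simulated unchanged arrays against 1 control gave r = 0.50, rho = 0.48 and 66.7%. At least 2-fold higher in both were 280 genes (107.5 in simulation, 61.3 for independent lists) and at least 2-fold lower in both were 716 (109.1 and 86.5, respectively). The covariance was 0.67 against 0.17 in simulation. The simulation gave the control array the same noise as the exposed arrays. The single control array cannot be split, and part or all of the excess may come from it. Genes such as mtl-1, hsp-12.6 and nlp-39 had nearly equal differences on both arrays, whereas the sperm and epidermal genes departed from the diagonal.

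**Figure D2:**
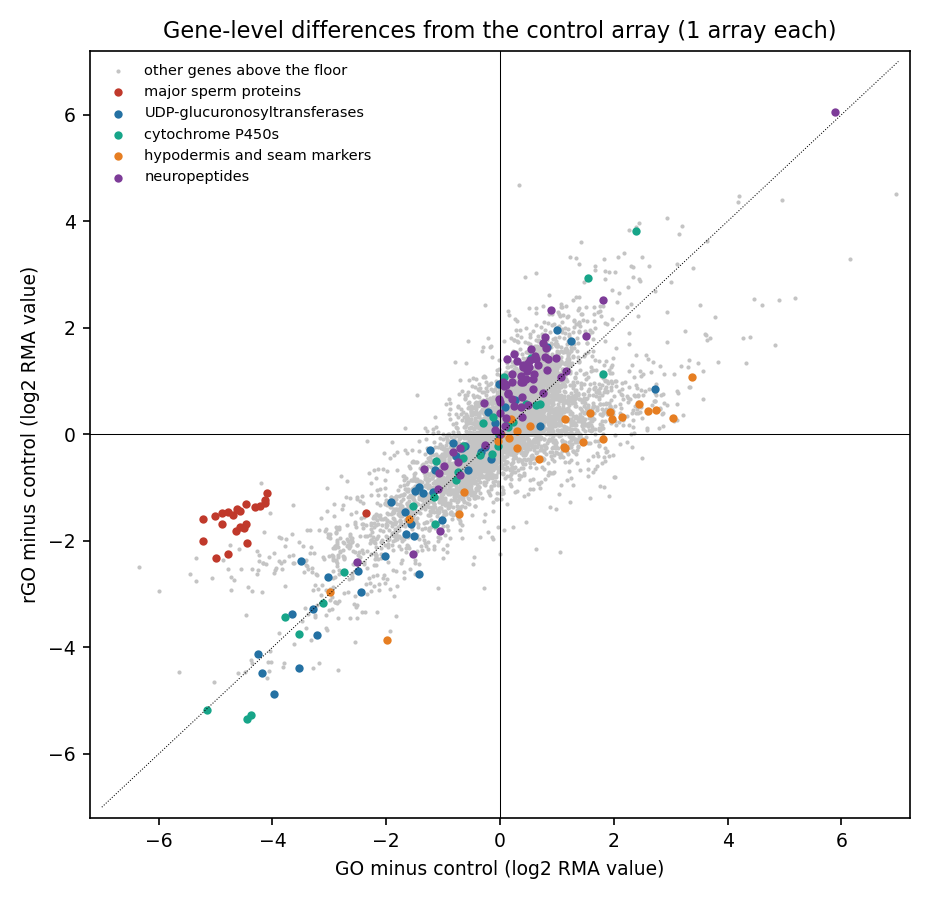
Log2 difference of each gene from the control array with GO (horizontal axis) and rGO (vertical axis), 1 array each, for 9454 genes above the floor, with 5 gene lists in colour and a dotted line of equal difference. Major sperm protein genes lie to the left of the line (medians -4.57 and -1.52) and hypodermis and seam markers to its right (1.12 and 0.00).

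**Figure D3:**
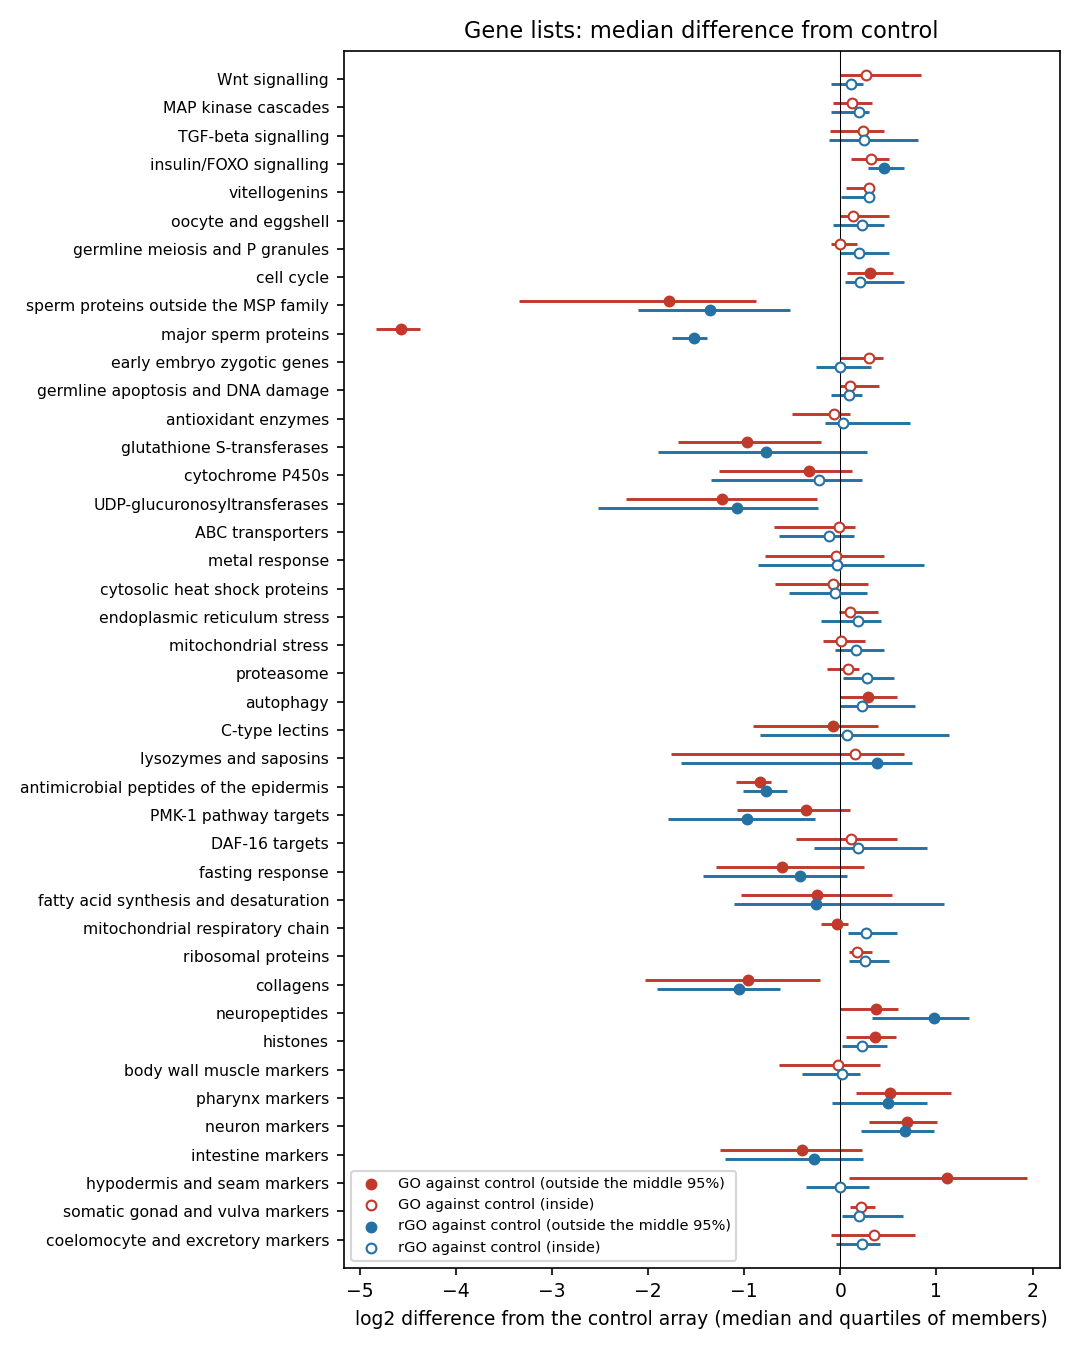
Median log2 difference from the control array of each list, for GO (red) and rGO (blue), with bars from the first to the third quartile of the list's genes. Filled circles are medians outside the middle 95% of 10000 expression-matched random lists, as for UDP-glucuronosyltransferases at -1.23 and -1.07.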

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

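All tests weighed here were chosen after the patterns were seen; for late embryo genes alone, the bound of the first test was set before the values of the list were seen. A pair of named genes was picked out because the differences from control had opposite signs with GO and rGO. Y102A11A.5 was at +1.91 with GO and -1.15 with rGO, and its control and rGO levels were both below the floor on dim genes. ZK1025.3 was at +1.06 and -2.21. With 1 array per group this opposite direction was not tested. Of 9454 genes, 5 differed by at least 1 unit in opposite directions, against 3.33 in simulation. The simulated noise was taken from the GO minus rGO differences themselves, so 3.33 is no separate baseline for this count. With values below 6.24 set to it, ZK1025.3 was only 1.53-fold lower with rGO and Y102A11A.5 only 1.05-fold, which leaves 3 of the 5 at 2-fold in both directions.

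Other values stand out in data outside the gene comparisons. Within pairs of probe sets, the 3′ to 5′ gap of the poly-A control transcripts exceeded that on the control array by a median of 0.90 with GO and 0.34 with rGO, and that of the worm control transcripts by a median of 0.32 with GO. Most poly-A 5′ probe sets were below 6.24 on the GO array, so the poly-A excess with GO is not exact. Among 1782 probe sets with no gene or several, 43 were at least 2-fold higher with GO and 43 with rGO, which was 7.01% of 613 and 7.03% of 612 above the floor, and 111 and 115 were at least 2-fold lower.

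The first pattern is the lower level of sperm transcripts on the GO array. Poorer labelling of short, abundant transcripts is argued against by the ribosomal protein genes, also short, whose median was 0.17. Sperm genes outside the major sperm protein family had a median of -1.78, which is part of the pattern, while that of the meiosis list was 0.00. A smaller sperm-producing share of the germline or fewer sperm per worm may account for the pattern, but no separate measure of either was available. An effect of GO on sperm stays open as the biological explanation of such a share, and so does a difference in age or handling between single cultures, neither of which was tested.

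The next pattern is the lower collagens beside the higher epidermal markers on the GO array. Against all worms being younger than adult stands the oocyte and eggshell median of 0.13. A smaller germline share would need a collagen median above 0. It was -0.96, with an upper quartile of -0.21 (-0.77 and -0.21 without probe sets that share probes). That low median is the pattern itself, so it is no separate test of this share. For the higher epidermal genes a smaller germline share cannot be told apart from other causes. Neuron (0.69) and hypodermis (1.12) medians were above 0 as it would need, and intestine (-0.40) and muscle (-0.02) medians were not. Without probe sets that share probes, however, intestine and hypodermis were at -0.06 and 0.33. Of the germline lists, sperm genes were lower as a smaller germline share would need. Oocyte and eggshell (0.13) and meiosis and P granule (0.00) medians were not lower. The processing makes array-wide distributions equal, so medians near 0 do not settle the size of that share. Late embryos or hatched larvae in the GO sample may contribute to the higher genes, as late embryonic epidermis genes had a median of 0.60 (19 genes, percentile 99.8), 0.41 without probe sets that share probes (percentile 98.2), and 0.55 over all 21 measured members (percentile 99.96), against 0.016 with rGO over the same 21. Over the 14 above the floor in both comparisons the GO median was 0.33 (percentile 96.5), but that choice leaves out genes high with GO alone. The list is made of epidermis genes, so any rise of epidermal transcripts would raise it and it cannot tell late embryos apart from that. An effect of GO on the epidermis stays open and untested.

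The last pattern is the lower level of detoxification genes on both exposed arrays. A smaller share of intestine RNA cannot be told apart from an exposure effect, since the medians of the intestine markers lay 0.40 (GO) and 0.33 (rGO) above those of the 100 detoxification genes, although without probe sets that share probes the intestine medians were -0.06 and 0.10 and these gaps 0.71 and 0.77. Whether the control worms were closer to the fed state cannot be told apart from an exposure effect: the fasting-induced genes had medians of 0.044 (GO) and -0.11 (rGO), but members went both ways, with hacd-1 at -1.75 and -1.53 and lipl-2 at +1.33 and +3.31. An unusual control array cannot be told apart from a shared effect either, since either would raise the covariance of both differences, which exceeded the simulated one by 0.49, and a further control array would be needed. An effect of both materials stays open and untested.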

How the results depend on the processing

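Leaving out probe sets that share probes was chosen after seeing the data. Of the list medians under the alternatives, 1036 kept their side of the middle 95%, 47 newly lay outside it, 30 moved inside, and 7 that had lain outside changed sign. Of the 1036 and 47, 43 and 4 also had the opposite sign, having lain inside as reported. For named genes at the 2-fold line, 3305 kept their side (3 under 2-fold with the opposite sign), 23 newly passed it, 36 no longer did and 0 past it changed sign. The correlation of the GO and rGO differences ranged from 0.780 to 0.813. Apart from the floor at the 75th percentile and other thresholds, counts higher and lower were 622 to 898 and 676 to 1073 (GO against control), 557 to 792 and 658 to 1018 (rGO against control), and 401 to 620 and 229 to 371 (GO against rGO). Fewer genes entered with the floor at the 75th percentile, which gave 287 and 464, 418 and 472, and 183 and 179 in the same order. By construction, 1.5-fold gave 1660 and 1397, 1735 and 1466, and 950 and 899, and 3-fold gave 326 and 551, 240 and 480, and 190 and 95. For list medians that moved across the middle 95% or reversed, the cause was not tested. After a further quantile normalisation the GO against control medians were 0.40 (Wnt, now above) and 0.0024 (respiratory chain, reversed in sign but still below). That of oocyte genes for GO against rGO was 0.14 (now above). With no floor, early embryo genes were at 0.28 (GO against control) and 0.24 (GO against rGO), now above, and TGF-beta for GO against rGO at -0.17, now inside. The floor at the 75th percentile gave for GO against rGO 0.13 (MAP kinase, now above), 0.13 (TGF-beta, reversed), -0.11 (meiosis, now inside) and -0.057 (collagens, reversed), and 0.39 for insulin/FOXO with rGO (now inside). With the brightest probe set per gene, TGF-beta (0.037, reversed) and early embryo (0.37, now above) moved for GO against rGO, and oocyte (0.21, now above) and cell cycle (0.15, now inside) for GO against control. Unmatched random lists put early embryo genes (0.24, GO against rGO) above. Without probe sets that share probes, TGF-beta (0.00073, GO against rGO), fatty acid genes (0.012, GO against control) and intestine markers (0.10, rGO against control) reversed, while insulin/FOXO with rGO (0.36), meiosis for GO against rGO (-0.14) and cell cycle for GO against control (0) moved inside. No value was possible for 8 list medians at the higher floor and 6 without shared probe sets (major sperm proteins and vitellogenins), as too few genes remained. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate; the deposited values are already log2, so no other log offset applied. Signal over background limits the folds: where the dimmer array was below 6.24, only a bound is given.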

Other observations

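All values here were looked at after the main comparisons. Probe sets for ribosomal RNA were higher on both exposed arrays. The ribosomal RNA gene rrn-3.1 had a log2 level of 9.05 on the control array, 13.25 on the GO array and 13.51 on the rGO array, as the mean of 5 probe sets whose differences between GO and control lay over 1 unit apart. The ribosomal RNA pseudogene rrn-3.56, whose probe set shares probes, was at 7.67, 8.63 and 9.37.

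The further 3 genes that differed at least 2-fold from control in opposite directions were all higher with GO and lower with rGO: R02E4.1 (+1.23 and -1.27), R12E2.15 (+1.58 with GO) and ifp-1, an intermediate filament gene (+1.03 and -1.12). Among late embryonic epidermis genes, hch-1, the hatching enzyme gene (+3.33), cut-5 (+2.54) and dex-1 (+2.12) were higher with GO, with cut-5 and dex-1 below background on the control array (5.08 and 5.59), and dpy-31 was lower (-1.01), and the probe sets of dex-1 differed by 2.13.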
